A study of Homo sapiens with 8 samples.

How the data were processed

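The series measured where the progesterone receptor (PR) and chromatin marks lie in the genome of T47D-MTVL cells by chromatin immunoprecipitation followed by sequencing (ChIP-seq). In 5 samples PR was precipitated from cells that were unstimulated (0 min) or had been given 10 nM of the progestin R5020 for 5, 30, 60 or 360 min. In 3 further samples of unstimulated cells the targets were histone H3 monomethylated at lysine 4 (H3K4me1), H3 trimethylated at lysine 4 (H3K4me3) and RNA polymerase II. Per the labels' protocols, cells spent 48 h in medium with charcoal-treated serum and 1 day without serum before hormone, and were fixed in 1% formaldehyde for 10 min. Each of these 8 groups holds 1 sample, so none of the differences between groups has a replicate check and no p-value was computed between samples.

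The PR lists and the chromatin lists were deposited by the authors as regions (chromosome, start, end) on hg19, per the file headers and the submitters' processing notes, with 1 list per sample. They carry no height, peak score or read number. The aligner, the peak caller, its thresholds, any input control and the read depth are not given in the sources used here. A region's absence from a list is therefore not evidence that the region was unbound, and differences in depth or threshold between libraries would change the length of a list. Coordinates are printed as the lists give them.

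A further table, also deposited by the authors, describes each PR site of the 60 min list. Per the file headers it holds, in each of 2 conditions (unstimulated and R5020), a normalized number of reads from sequencing of DNA left after digestion with micrococcal nuclease (MNase), which cuts DNA between nucleosomes. The authors' normalized read numbers are whole numbers, and were handled as a score and not as raw reads, and how they were normalized is not given in the sources used here. The table's ratio column was made by the authors and equals the unstimulated value divided by the R5020 value within 0.005 at each of the 24433 sites that have one. The ratio is blank at 3 sites, those with an R5020 value of 0. All 24436 sites of the table match the 60 min list exactly. The last columns say whether a site overlaps H3K4me1 and H3K4me3 regions. One header line names H3K4me1 over both, but each of the 1242 sites marked in the second column overlaps the H3K4me3 list. The smallest overlap among sites the authors marked was 10 bp for each mark, and 18 sites that overlap an H3K4me1 region by at most 8 bp and 10 sites that overlap an H3K4me3 region by at most 9 bp are not marked. The MNase libraries themselves are not among the 8 samples and were not analysed here.

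From these files, sites of different lists were called shared where they overlap by 1 bp or more. Sites of all 5 PR lists that overlap were merged into a union, and each merged site was classed by the times that list it. Shares carry exact (Clopper-Pearson) 95% intervals over the sites of 1 library. They cover counting error only and not variation between cultures. The chance level of a share is its mean over 1000 placements in which each site of a PR list was put at a random place on its own chromosome, whose length was taken as the last base listed in any file. Because those lengths include assembly gaps and closed chromatin, each site was also moved by a random 10 to 100 kb, 100 times per list, as a local level. MNase values were compared between classes of sites as medians, and the 95% interval of a difference came from 1000 resamplings of whole chromosomes (500 for differences within 20 equal groups of sites by unstimulated read density, 200 for rank correlations across sites and for the alternatives). These intervals describe sites within the authors' table. Rank correlations (Spearman's rho) are across sites or across 5 Mb bins, which are not independent replicates. Intervals of those across bins came from 1000 resamplings of single bins. Neighbouring bins have similar read densities, so these intervals are likely too narrow. Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and Matplotlib 3.10.9 were used.

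The overlap code was tested on simulated data. Copies of the 60 min list in which 10.1%, 39.9% and 79.8% of sites stayed within 50 bp of their place and the rest were moved away gave shares of 11.0%, 40.4% and 80.0%, and matched a direct search without exception on chromosomes 21 and 22. With 100 resamplings, the 95% interval over chromosomes covered a planted difference between H3K4me3 classes in 92.5% of 40 simulated tables, slightly below its nominal level. The simulated values were independent between sites, so this coverage says nothing about sites that resemble their neighbours. When class labels were drawn by unstimulated reads alone, the difference in log2 ratio had a median of 0.14 over 40 simulations, and within groups of equal unstimulated reads it lay between -0.03 and 0.03. Labels and groups used the same read density here, so values near 0 followed by construction and only check the code.

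The groups, comparisons, gene lists and part of the alternatives were fixed before the data were examined, on the assumption that the lists hold a score per site. The rule for named sites took the 10 leading PR sites at 60 min, the 5 leading sites of each other PR list, sites listed at 0 min and each later time, the leading sites of the 360 min alone and early classes, and the leading regions of each chromatin list. With no score in the lists, sites were ranked by the number of times that list them and then by width, as the rule foresaw. No gene annotation on hg19 was used here, and the lists name no genes. The planned positions relative to genes and the 11 fixed gene lists were therefore not analysed, and gene or exon context is not stated for any site. Alternatives that rank by score could not be run. In their place the wider 50% of the regions, and equal numbers of the widest sites, were tried after the lists had been seen.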

Results

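PR is a hormone-activated transcription factor, and R5020 (promegestone) is a synthetic progestin that binds it. T47D-MTVL is a human luminal breast cancer line that carries a progestin-responsive reporter under the mouse mammary tumour virus promoter. The data comprised 5 lists of PR sites, from unstimulated cells and from cells given 10 nM R5020 for 5, 30, 60 and 360 min, and 3 lists of regions marked by H3K4me1, H3K4me3 and RNA polymerase II in unstimulated cells. H3K4me1 is found at enhancers and around promoters, H3K4me3 at active promoters, and RNA polymerase II where genes are transcribed. A table of MNase reads at the 60 min PR sites in unstimulated and R5020-treated cells completed the set. There was 1 library per group throughout, and the read depth of the libraries is unknown.

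The first comparison asked how many genomic sites PR occupied before hormone and how soon after R5020 this changed. In unstimulated cells 844 PR sites were listed. After 5 min of R5020 the list held 22973 sites, 27.2 times as many, and it then stayed near that length, with 25872 sites at 30 min, 24436 at 60 min and 23841 at 360 min. The sites were narrow at each time. Their median width was 232 bp at 0 min (quartiles 203 and 275 bp), 269 bp at 5 min, 285 bp at 30 min, 313 bp at 60 min (260 and 393 bp) and 265 bp at 360 min. PR sites covered 0.218 Mb at 0 min and 8.33 Mb at 60 min. Without replicates or depths, neither the step from 844 to 22973 sites nor the differences among the 4 lists with hormone can be set against the spread between libraries. The step remained when sites within 500 bp were merged and when chromosomes X, Y and M were left out. These settings remove few sites and could not have undone it.

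**Figure D1:**
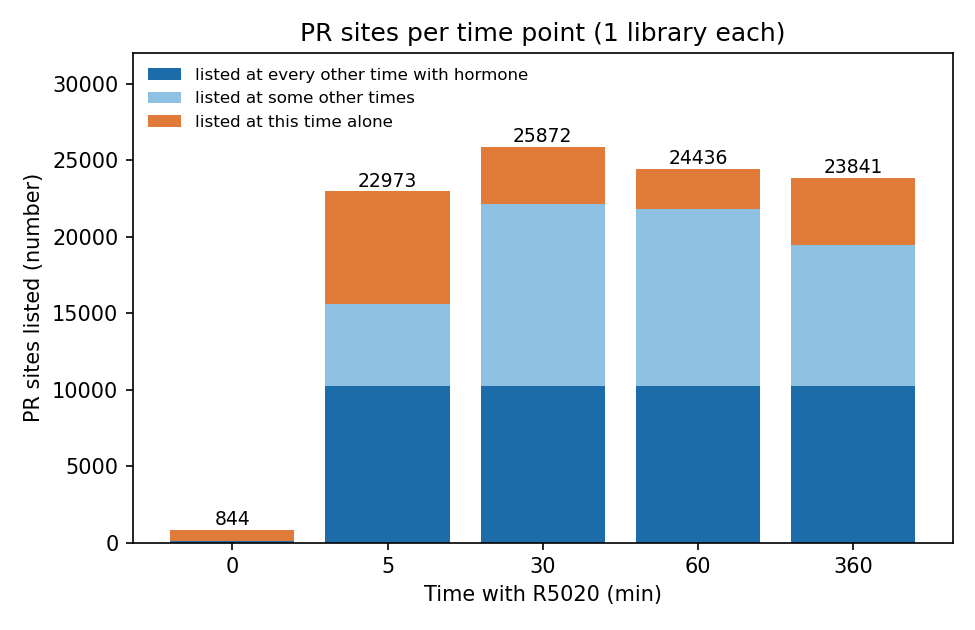
Number of PR sites listed at each time with R5020 (x axis, min), 1 library per bar, coloured by whether a site is listed at every other time with hormone, at some other times or at that time alone. The bars hold 844, 22973, 25872, 24436 and 23841 sites. The 5 min bar has the largest number listed at its own time alone, 7371 sites (32.1%), and the 0 min bar the largest share, 87.1%.

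The second comparison asked whether PR stayed at the same sites over the time course. A large common set was present from 5 min on: merging the 5 lists gave 43784 sites, of which 10001 (22.8%) were listed at all 4 times with hormone and not at 0 min. A further 4653 sites were listed at 30, 60 and 360 min but not at 5 min. The sites listed at 1 time alone numbered 7371 for 5 min, 3729 for 30 min, 2663 for 60 min, 4421 for 360 min and 735 for 0 min. The 5 min list thus differed most from the others with hormone, with 32.1% of its sites (95% interval 31.5 to 32.7%) listed at no other time, against 14.4% of the 30 min list, 10.9% of the 60 min list and 18.5% of the 360 min list. These class sizes depended on the sites taken: from the wider 50% of each list with hormone, 3469 sites were at all 4 times with hormone, 3519 at 5 min alone and 1814 at 30, 60 and 360 min but not 5 min.

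Of the 24436 sites at 60 min, 77.6% (77.0 to 78.1%) were listed at 30 min, 70.6% (70.0 to 71.1%) at 360 min and 53.7% (53.1 to 54.3%) at 5 min. Random placement of the 60 min sites gave 0.526% in the 360 min list, with a range of 0.389 to 0.671% over 1000 placements, and 0.515% in the 5 min list. The shared sites were wider. Of the narrowest quartile of 60 min sites (median 235 bp), 42.3% (41.1 to 43.6%) were listed at 5 min and 57.0% (55.8 to 58.3%) at 360 min, and of the widest quartile (median 471 bp) 60.9% (59.7 to 62.1%) and 77.5% (76.4 to 78.6%). Sites moved by 10 to 100 kb gave 1.27% in the 360 min list, so that the ratio to the comparison level is 134 for random placement and 55.8 for these moved sites.

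Most sites listed in unstimulated cells were not listed after hormone. Of the 844 sites at 0 min, 735 (87.1%, 84.6 to 89.3%) were absent from each later list and 89 (10.5%, 8.55 to 12.8%) were listed at 60 min, against 0.561% by random placement. At all 4 later times, 72 of the 844 were listed. In the opposite direction, 0.364% (0.293 to 0.448%) of the 60 min sites were listed at 0 min. With a reciprocal overlap of at least 50% these shares were lower, 5.92% and 0.205%.

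The named sites were those listed at each of the 5 times, ordered by width at 60 min. The widest lay on chromosome 19 from 41426776 to 41427688 (912 bp). It was followed by sites on chromosome 3 from 186358062 to 186358861 (799 bp), chromosome 12 from 48146836 to 48147588 (752 bp), chromosome 5 from 154448167 to 154448909 (742 bp) and chromosome 7 from 34083421 to 34084131 (710 bp). All 10 leading sites overlapped an H3K4me1 region. Only 2 of them, on chromosome 3 from 187526432 to 187527133 and on chromosome 9 from 140506476 to 140507046, also overlapped H3K4me3 and RNA polymerase II regions. The remaining 3 were on chromosome 11 from 129959240 to 129959831, chromosome 3 from 127022967 to 127023535 and chromosome 12 from 69833923 to 69834476. The chromosome 19 site led at 5 min (975 bp) and 360 min (935 bp) as well, and the chromosome 12 site led at 30 min (951 bp). The leading site at 0 min was another one, on chromosome 9 from 68421108 to 68422374 (1266 bp), overlapping all 3 kinds of chromatin region. It lay in a stretch of very high read density: the 9 sites of the 60 min list between 68 and 69 Mb of chromosome 9 had a median of 1218 MNase reads in unstimulated cells in the authors' deposited table, against 97 over all sites. None of the 5 widest sites listed at 360 min alone overlapped a region of any of the 3 chromatin lists, in a class with 26.5% of sites in H3K4me1 regions, against 93.3% of the merged sites listed at 0 min and a later time. The widest of these were on chromosome 9 from 123236622 to 123237516 and chromosome 21 from 38328008 to 38328753. Of the 5 leading sites listed at 5 min but not at 60 or 360 min, 4 overlapped H3K4me1 regions, and the widest of the 5, on chromosome 3 from 70854589 to 70855659, did not.

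The third comparison asked in what chromatin PR sites lay before the hormone was given. About as many PR sites were inside as outside regions with H3K4me1, and few were in regions with H3K4me3 or RNA polymerase II. At 60 min, 11789 of 24436 sites (48.2%, 47.6 to 48.9%) overlapped H3K4me1 regions, 1252 (5.12%, 4.85 to 5.41%) overlapped H3K4me3 regions and 2180 (8.92%, 8.57 to 9.29%) overlapped RNA polymerase II regions. None of the 3 kinds was present at 12305 sites (50.4%). Each share was above chance: random placement gave 9.73% for H3K4me1, 0.810% for H3K4me3 and 1.04% for RNA polymerase II. Against sites moved by 10 to 100 kb the ratios were smaller but above 1, at 2.38 for H3K4me1, 3.67 for H3K4me3 and 3.78 for RNA polymerase II. Counting sites within 1 kb of a region gave 8.70% for H3K4me3 and 14.0% for RNA polymerase II.

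The H3K4me1 share differed between the lists with hormone by more than counting error, at 51.0% (50.4 to 51.7%) for 5 min, 47.3% (46.7 to 48.0%) for 30 min and 45.1% (44.4 to 45.7%) for 360 min. The 48.1% (44.7 to 51.5%) at 0 min was close to the 60 min share, but this depended on the sites taken. Without chromosome 3 the shares were 43.2% (39.2 to 47.2%) at 0 min and 47.4% (46.7 to 48.0%) at 60 min, and for the wider 50% of each list 58.1% (53.2 to 62.8%) and 49.97% (49.1 to 50.9%). H3K4me3 and RNA polymerase II regions held a larger share of the sites of unstimulated cells. H3K4me3 regions held 11.6% (9.53 to 14.0%) of the 0 min sites, against 4.45%, 4.27%, 5.12% and 4.19% at 5, 30, 60 and 360 min, and RNA polymerase II regions held 13.2% (10.9 to 15.6%), against 9.11%, 8.03%, 8.92% and 7.74%. The 0 min sites also lay in neighbourhoods richer in H3K4me1: moved by 10 to 100 kb they fell in such regions in 33.8% of cases, against 20.3% for the 60 min sites, so that the ratio of observed to moved was 1.42 at 0 min. For RNA polymerase II this ratio was 4.11 at 0 min, 4.24 at 5 min and 3.78 at 60 min, and for H3K4me3 it was 5.93, 3.53 and 3.67. The H3K4me1 list was itself uneven, from 3.83 regions per Mb on chromosome X to 59.3 on chromosome 17, with 42.4 on chromosome 3. Whether regional read density or DNA copies shape that list was not tested. With only the wider 50% of the chromatin regions, the H3K4me3 share at 0 min, 4.27% (3.01 to 5.86%), could no longer be told from the 3.49% at 60 min, and the RNA polymerase II shares were 7.70% (5.99 to 9.71%) and 5.97% (5.68 to 6.28%).

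**Figure D2:**
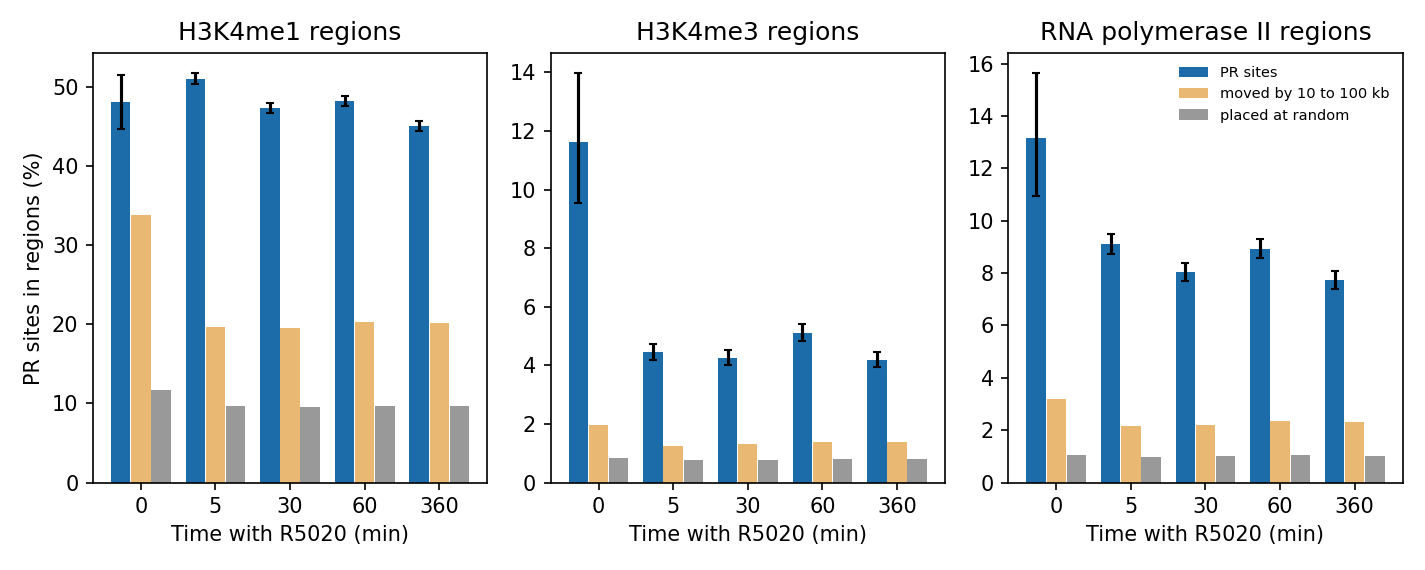
Share of PR sites (y axis, %) that overlap H3K4me1, H3K4me3 and RNA polymerase II regions of unstimulated cells at each time with R5020 (x axis, min). Blue bars are PR sites with exact 95% intervals over sites, tan bars the same sites moved by 10 to 100 kb and grey bars sites placed at random. For H3K4me1 the blue bars lie between 45.1% and 51.0% and the grey bars between 9.60% and 11.7%.

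Sites listed at all 4 times with hormone lay in H3K4me1 regions more often than those listed at 1 time alone. Of the 10001 sites listed at all 4 times with hormone, 60.3% (59.3 to 61.2%) overlapped H3K4me1 regions, 6.10% (5.64 to 6.59%) H3K4me3 regions and 12.4% (11.8 to 13.1%) RNA polymerase II regions. Of sites listed at 360 min alone these shares were 26.5% (25.2 to 27.8%), 1.85% and 3.03%. Sites listed at 5 min alone were in H3K4me1 regions in 36.2% (35.1 to 37.3%) of cases, sites at 30 min alone in 32.0%, sites at 60 min alone in 36.7% and sites at 0 min alone in 41.5% (37.9 to 45.2%). For sites listed at 30, 60 and 360 min but not at 5 min the share was in the range of the single-time classes, at 35.0% (33.7 to 36.4%). Among the 105 merged sites listed at 0 min and at least 1 later time, 93.3% (86.7 to 97.3%) were in H3K4me1 regions, 34.3% (25.3 to 44.2%) in H3K4me3 regions and 46.7% (36.9 to 56.7%) in RNA polymerase II regions. This class includes sites in the stretch of very high read density on chromosome 9 between 68 and 69 Mb. There the 60 min sites had a median of 478 unstimulated MNase reads per 100 bp in the authors' deposited table, against 30.3 over all sites. How far such stretches shape the shares of this class was not tested. Merged sites listed at more times are also wider (median 403 bp at all 4 times and 226 bp at 360 min alone). Counting only midpoints, the H3K4me1 shares of these classes were 58.7% and 25.8%.

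The 3 chromatin lists of unstimulated cells differed in extent. H3K4me1 was listed in 73263 regions with a median width of 2124 bp that together covered 231.7 Mb, H3K4me3 in 22593 regions of 634 bp covering 16.7 Mb, and RNA polymerase II in 31128 regions of 482 bp covering 19.5 Mb. Most H3K4me3 regions overlapped an H3K4me1 region (73.3%, 72.8 to 73.9%) and an RNA polymerase II region (67.1%, 66.4 to 67.7%), and 72.6% (72.1 to 73.1%) of RNA polymerase II regions overlapped an H3K4me1 region. PR at 60 min was found in 12.2% of the H3K4me1 regions, 5.56% of the H3K4me3 regions and 6.84% of the RNA polymerase II regions. The widest H3K4me1 region lay on chromosome 16 from 85365139 to 85797385, the widest H3K4me3 region on chromosome 10 from 8096657 to 8104422 (7765 bp), and the widest RNA polymerase II region on chromosome 17 from 80036996 to 80048529 (11533 bp). The shares between chromatin lists rest on overlaps of 1 bp between regions of unequal width. With a reciprocal overlap of 50% they were 4.17%, 26.5% and 1.39%, but a narrow region wholly inside a much wider H3K4me1 region fails that rule.

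The fourth comparison used the MNase reads to ask how nucleosome-sized DNA at PR sites differed between unstimulated and R5020-treated cells. In the authors' deposited table the median over the 24436 sites was 97 normalized reads per site in unstimulated cells and 75 after R5020. The median ratio of unstimulated to R5020 in the authors' deposited table was 1.29 (quartiles 1.04 and 1.66), and 19051 sites (78.0%) had a ratio above 1. One scaling factor between the MNase libraries would move all these ratios together, so the classes of sites were compared with each other.

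The ratio was higher at PR sites in RNA polymerase II, H3K4me3 or H3K4me1 regions than at other sites. In the authors' deposited table the median ratio was 2.03 at the 2180 sites in RNA polymerase II regions and 1.26 at the others, 1.61 times higher (interval over chromosomes 1.57 to 1.66). Sites with H3K4me3 had 1.97 against 1.28 in the authors' deposited table, 1.54 times higher (1.48 to 1.60), and sites with H3K4me1 had 1.5 against 1.15, 1.30 times higher (1.27 to 1.34). Each of these 3 differences had the same direction on all 23 chromosomes. Without the upper and lower 5% of ratios in the authors' deposited table, the difference for H3K4me3 was 0.40 on the log2 scale, against 0.62 with all sites. Combining the marks, the median ratio from the authors' deposited table was 1.14 at the 12437 sites with neither histone mark, 1.47 with H3K4me1 alone, 1.77 at the 228 sites with H3K4me3 alone, 2.00 with both and 2.25 at the 676 sites in all 3 kinds of region. A ratio above 2 in the authors' deposited table was found at 51.2% of sites in RNA polymerase II regions and at 3.82% of sites with neither histone mark.

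Both sides of the ratio differed at sites in RNA polymerase II regions, of which 811 of 2180 (37.2%) were marked as H3K4me3 sites in the authors' deposited table. Per 100 bp, the authors' deposited table gave a median of 38.3 normalized reads in unstimulated cells at sites in RNA polymerase II regions and 29.6 at others, a difference of 8.70 (7.26 to 10.5). After R5020 the order was the opposite in the authors' deposited table, with 19.4 and 23.5, a difference of -4.03 (-5.39 to -2.63). At H3K4me1 sites the unstimulated value in the authors' deposited table was higher by 10.9 (8.67 to 12.8), and after R5020 the difference of 2.61 had an interval that included 0 (-0.026 to 4.94). Regional read density was not held equal in this comparison.

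The MNase ratio also differed with the times at which a site was listed. From the authors' deposited table, sites listed at all 4 times with hormone had a median ratio of 1.39 and sites listed at 60 min alone 1.23, 1.13 times higher (1.11 to 1.15). These classes also differed in chromatin. Of the merged sites, 60.3% and 36.7% lay in H3K4me1 regions, and 12.4% and 6.61% in RNA polymerase II regions. Chromatin class was not held equal, so its part in this difference cannot be told from that of the times listed. The 89 sites listed at both 0 and 60 min had 1.96 in the authors' deposited table against 1.29 at the others, 1.52 times higher (1.39 to 1.71). These sites also differed in chromatin class, since 42 of the 89 (47.2%, 36.5 to 58.1%) lay in RNA polymerase II regions. In H3K4me1 regions lay 83 of the 89 (93.3%), against 48.2% of all 60 min sites. Their median unstimulated read density in the authors' deposited table was 53.4 per 100 bp, against 30.25 at the others. This difference was 23.1 (17.4 to 44.6). In a split chosen after the values were seen, the median ratios from the authors' deposited table were 2.54 and 2.03 within RNA polymerase II regions, a log2 difference of 0.33 (0.09 to 0.54), and 1.81 and 1.26 outside them, a difference of 0.52 (0.39 to 0.60). Neither H3K4me1 nor unstimulated read density was held equal in this split. It therefore cannot tell whether the ratio differs at equal chromatin class and read density. Among the 10 leading sites at 60 min, the ratio in the authors' deposited table ranged from 0.99 on chromosome 7 (34083421 to 34084131) to 4.24 on chromosome 3 (127022967 to 127023535), where reads went from 89 to 21. On chromosome 19 (41426776 to 41427688) the authors' deposited table gave 321 and 125 reads, a ratio of 2.57.

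**Figure D3:**
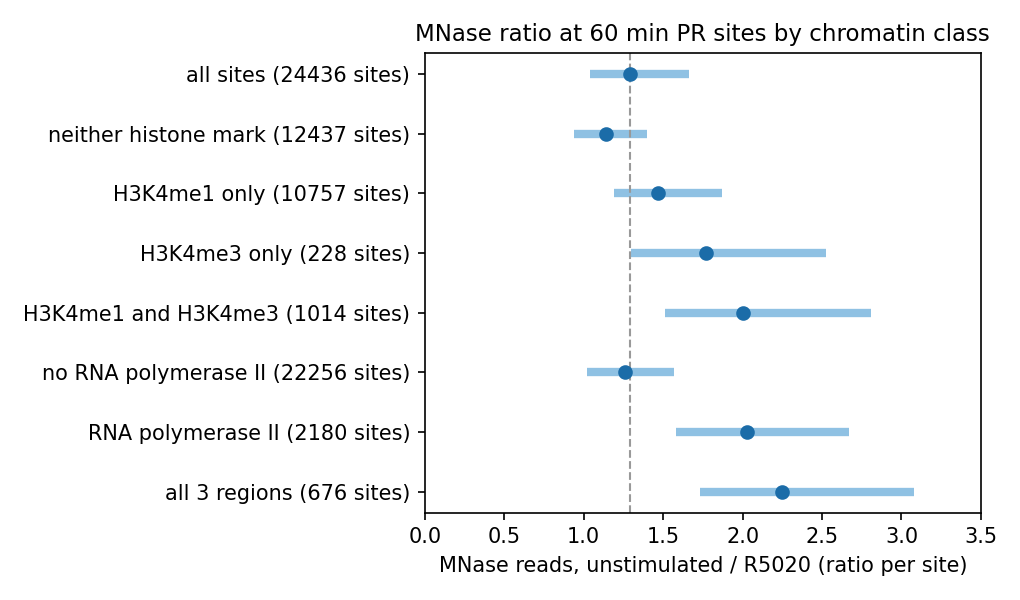
Ratio of MNase reads in unstimulated cells to those after R5020 (x axis) at 60 min PR sites, by overlap with chromatin regions of unstimulated cells (y axis, with the number of sites). Points are medians and bars run from the lower to the upper quartile over sites in the authors' deposited table, and the dashed line is the median of all sites, 1.29. Medians run from 1.14 with neither histone mark to 2.25 in all 3 kinds of region.

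The sites were not spread alike over the chromosomes. Chromosome 3 held 223 of the 844 sites at 0 min (26.4%, 23.5 to 29.5%), against 10.1% (9.75 to 10.5%) of the 5 min sites, 8.88% at 30 min, 8.47% (8.12 to 8.82%) at 60 min and 8.41% at 360 min. Of the 735 sites listed at 0 min alone, 170 (23.1%) lay on chromosome 3 from 150 Mb to its end, a boundary chosen after the counts were seen, and 36 on the rest of that chromosome. In the same part, 546 of 1177 merged sites listed at 5 min (46.4%) were listed at that time alone, against 33.2% on the rest of chromosome 3 and 31.8% on other chromosomes. In the authors' deposited table, MNase reads of unstimulated cells at 60 min sites with neither histone mark had a median of 45.9 per 100 bp in that part, 27.2 on the rest of chromosome 3 and 24.9 on other chromosomes.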

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

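The list of RNA polymerase II regions holds 15 regions on the mitochondrial chromosome, covering 13299 bp, which is above the 3 regions taken as the limit for a count of 0, and no control library was used here. The H3K4me3 list holds 3 mitochondrial regions, and the 5 PR lists and the H3K4me1 list hold none.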

How the results depend on the processing

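Alternatives by width, moves of 10 to 100 kb and results without chromosome 3 were chosen after seeing the data, and the others before. A share or ratio counted as unchanged when it stayed within the exact 95% interval of the reported share, a number of sites when it stayed within 1.5 times, and a difference in log2 MNase ratio when it kept its direction with an interval that excluded 0. By these rules 84 of the 195 alternative values were unchanged, among them all 24 for the MNase differences, of which 6 leave out only the 3 sites without a ratio and so test nothing. None of these 24 changed sign and none of the 12 alternative ratios to chance fell below 1, while shares and numbers of sites have no sign to change. The MNase differences kept their direction but not their size: without the upper and lower 5% of sites they were 0.30 for H3K4me1, 0.40 for H3K4me3 and 0.49 for RNA polymerase II, against 0.38, 0.62 and 0.69. The numbers of sites per time stayed within 1.5 times under each alternative run, but these alternatives remove few sites. Required to overlap reciprocally by 50%, 60 min sites were listed at 0, 5, 30 and 360 min in 0.205%, 49.3%, 73.6% and 66.0% of cases, 5 min sites at 60 min in 52.4% and 0 min sites at 60 min in 5.92%. H3K4me3 regions then overlapped H3K4me1 in 4.17% and RNA polymerase II in 26.5%, and RNA polymerase II regions overlapped H3K4me1 in 1.39%. A narrow region wholly inside a much wider H3K4me1 region fails this rule. The 4.17% and 1.39% therefore cannot tell whether these regions lie inside H3K4me1 regions. With sites within 500 bp taken as shared, the 60 min shares were 0.507%, 56.4%, 79.2% and 72.7%, the 5 min share at 60 min was 60.5%, the narrowest quartile gave 46.98% at 5 min and 60.7% at 360 min, and the widest 62.5% and 78.9%. With equal numbers of the widest sites, 60 min sites were listed at 5, 30 and 360 min in 54.9%, 75.2% and 71.1%, and 5 min sites at 60 min in 55.4%. Ratios to chance of the 60 min sites for the 360 min, 5 min, H3K4me1, H3K4me3 and RNA polymerase II lists went from 134, 104, 4.96, 6.32 and 8.60 to 98.0, 70.5, 3.52, 4.57 and 6.06 with sites shifted by 1 Mb, and to 55.8, 44.3, 2.38, 3.67 and 3.78 with sites moved by 10 to 100 kb. For 0 min sites in H3K4me1 the ratio went from 4.10 to 1.86 and 1.42. From the wider 50% of each list with hormone, 3519 sites were at 5 min alone, 2332 at 30 min alone, 2658 at 360 min alone, 3469 at all 4 times with hormone and 1814 at 30, 60 and 360 min but not 5 min, while 2637 were at 60 min alone and 766 at 0 min alone, so that 5 min alone and not all 4 times was the largest of these classes. For H3K4me1, H3K4me3 and RNA polymerase II, counting sites within 1 kb gave 54.6%, 15.5% and 18.7% at 0 min and 53.2%, 8.70% and 14.0% at 60 min. The wider 50% of the chromatin regions gave 40.6%, 4.27% and 7.70% at 0 min and 38.7%, 3.49% and 5.97% at 60 min. Midpoints gave 46.9%, 3.99% and 7.18% at 60 min. The wider 50% of PR sites gave 58.1%, 18.0% and 19.2% at 0 min and, for H3K4me1, 49.97% at 60 min. Without chromosome 3 the H3K4me1 shares were 43.2% at 0 min and 47.4% at 60 min. Sites at all 4 times with hormone were in H3K4me1 by midpoint in 58.7% and within 1 kb in 64.7%, and sites at 360 min alone within 1 kb in 31.4%. With the wider 50% of both lists, H3K4me3 overlapped H3K4me1 in 64.8% and RNA polymerase II in 67.8%, and RNA polymerase II overlapped H3K4me1 in 70.5%. Changes of the overlap rule widen or narrow shares by construction; for the other settings the cause was not tested. The alternatives ranked by score, and those of gene positions and gene lists, were not run, since the lists hold no scores and no hg19 annotation was used. Read depth is unknown, so how far it sets the length of each list cannot be judged. No paired analysis was possible because each group has 1 sample.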

Other observations

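PR sites were clustered. The median distance between neighbouring 60 min sites was 34.3 kb, against 81.5 kb when they were placed at random on their chromosomes, and 21.1% of neighbours were within 5 kb of each other. Counted by midpoint, H3K4me1 regions held 49.5 PR sites per Mb at 60 min and the rest of the genome 4.63, a ratio of 10.7. This ratio was 11.9 at 5 min and 9.498 at 360 min. The rest of the genome here includes assembly gaps, and no local level was computed for these densities or for the distances. The share of 60 min sites that overlapped H3K4me1 regions was 2.38 times that of the same sites moved by 10 to 100 kb. The 1 Mb window with most PR sites was on chromosome 16 from 85 to 86 Mb at 30, 60 and 360 min, with 86, 82 and 84 sites, against a median of 7 or 8 in windows with any site. At 5 min the leading window was on chromosome 12 from 116 to 117 Mb, with 72 sites, and at 0 min on chromosome 3 from 194 to 195 Mb, with 19.

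The widest H3K4me1 region, 432.2 kb on chromosome 16 from 85365139 to 85797385, overlapped 169 RNA polymerase II regions, 61 H3K4me3 regions and 52 PR sites at 60 min. In the authors' deposited table these 52 sites had a median of 86.0 MNase reads per 100 bp in unstimulated cells, 2.49 times the 34.6 of the 559 other H3K4me1 sites of the chromosome, and a median ratio of 2.27. At the extremes of the authors' deposited table chromatin classes differed. Of its 10 sites with the highest MNase ratio, each overlapped an H3K4me3 or RNA polymerase II region, and the site on chromosome 15 from 45003491 to 45003967 had 628 reads before and 70 after R5020, a ratio of 8.97. Several of these 10 ratios rest on few reads after R5020. The highest in the authors' deposited table, 29 on chromosome 18 from 77724480 to 77724702, came from 29 and 1 reads, and the next, 14.25 on chromosome 19, from 57 and 4. Of the 10 sites with the lowest ratio in the authors' deposited table, 9 overlapped none of the 3 kinds of region and 1, on chromosome 1 from 230887357 to 230887618, overlapped H3K4me1 and RNA polymerase II regions. The lowest ratio, 0.24, was on chromosome 14 from 51115980 to 51116226, with 18 and 76 reads. Both choices of sites were made after their values were seen. Across sites of the authors' deposited table, MNase reads before and after R5020 had a Spearman's rho of 0.78 (0.75 to 0.79 over chromosomes).

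Of the tests that follow, the one of read density against the 0 min alone sites was chosen after counts per chromosome had been seen, as were the repeats without chromosome 3 and the values by groups of bins, and the one of the MNase ratio at equal unstimulated reads after the ratios by class had been seen.

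Sites listed at 0 min alone were enriched at the end of chromosome 3, which held 170 of the 735 (23.1%), while 529 (72.0%) lay on other chromosomes. A candidate explanation is that regions with more DNA copies, or otherwise higher read density, yield more called sites. Across 556 bins of 5 Mb, the number of such sites followed the MNase read density of unstimulated cells at unmarked 60 min PR sites (rho 0.62, 0.56 to 0.67), also without chromosome 3 (0.61). The intervals resample single bins, although neighbouring bins are alike, and are likely too narrow. Of 5 equal groups of bins, the one with the highest density held 63.3% of the 683 such sites in these bins and 30.0% of the 23995 sites at 60 min. By rank, the density was related as closely to the number of 5 min sites per bin (rho 0.62, 0.56 to 0.67) and also to that of 60 min sites (0.54), but the group with the highest density held a smaller part of the 5 min sites, 31.4% of 22158. PR binding at marked elements before hormone stays open, since the share in H3K4me1 regions was 1.29 times (1.18 to 1.40) that of the moved sites, between the limits of 1.1 and 1.5 set for the test, while the ratios for H3K4me3 and RNA polymerase II regions, 4.37 (3.36 to 5.57) and 3.11 (2.42 to 3.94), were above both but rest on 8.03% and 8.57% of these sites.

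Sites listed at 5 min alone were the largest class listed at 1 time, and 3 explanations were set against each other. Weak regions near the limit of peak calling may account for part of them, but the lists hold no score, and width was used in its place. The median width of sites at 5 min alone was 0.767 times (0.758 to 0.776) that of 5 min sites also listed at 30, 60 and 360 min. The same ratio was 0.777 at 360 min, 0.731 at 30 min and 0.844 at 60 min, where 18.5%, 14.4% and 10.9% of sites stood alone. Wider sites also meet the overlap rule of 1 bp more easily, so these widths cannot tell whether sites at 5 min alone were weak. Regional read density was weakly related to the share of 5 min sites at 5 min alone (rho 0.13, 0.051 to 0.22, over 537 bins, and 0.0995 without chromosome 3). Its interval, which resamples single bins and is likely too narrow, held the limit of 0.1 set for the test. Early PR binding at marked elements stays possible. The share in H3K4me1 regions was 2.23 times (2.16 to 2.30) that of the moved sites. This ratio was the highest of the single-time classes (2.02 at 60 min alone, 2.01 at 30 min alone, 1.54 at 360 min alone and 1.29 at 0 min alone) and below the 2.65 of sites at all 4 times with hormone. The share itself, 36.2%, was no higher than the 36.7% at 60 min alone. For H3K4me3 the ratio was 2.35, against 4.37, 1.92, 4.56 and 1.43 at 0, 30, 60 and 360 min alone. For RNA polymerase II it was 3.26, against 3.11, 2.24, 3.35 and 1.62, so 5 min alone did not lead for these 2 lists. With 1 library per time, a difference between the 5 min culture or its depth and the others cannot be separated from time with hormone.

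The MNase ratio was higher at PR sites in H3K4me3 or RNA polymerase II regions. Across sites, unstimulated read density and the log2 ratio had a Spearman's rho of 0.35 (0.29 to 0.41). For RNA polymerase II regions the values argue against regression from high unstimulated reads. Within 20 equal groups of sites by unstimulated read density, the median difference in log2 ratio between sites in these regions and others was 0.61 (0.55 to 0.68), against 0.69 over all sites. This difference ranged from 0.51 to 1.25 over the 20 groups. Without these groups, the difference between sites in RNA polymerase II regions and others had the same direction on 23 of 23 chromosomes. This argues against differences between chromosomes as the cause. The differences for H3K4me3 and H3K4me1 regions were not compared at equal unstimulated reads, so regression stays open for them. A bias of MNase cutting or sequencing with base composition was not tested, since no genome sequence was used here. A biological reading, that R5020 lowers nucleosome-sized DNA most at PR sites in regions with RNA polymerase II or H3K4me3, remains a hypothesis, and sites without PR were not measured in the table, so a change of such regions independent of PR may give the same result.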
